A study of Mus musculus with 2 samples.

How the data were processed

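The series held 2 single-cell RNA libraries from female MMTV-PyMT mice, 1 labelled SR-A knockout and 1 labelled SR-A wild type. Genotypes were taken from the genotype label of each sample, and no sample was left unassigned. Per the labels' protocols, the suspensions went through the NextGEM 3' chemistry of 10x Genomics, a NextSeq 500 read the libraries, and the aim was 10000 cells and 20000 reads for each cell. This assay counts unique molecular identifiers (UMIs) near the 3' end of polyadenylated transcripts. A gene count from it carries no position within the gene.

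The deposited values were counts, whole-number UMIs per gene and cell barcode in a sparse matrix, with no normalization in the files. Cell Ranger (versions 7.1 and 6.0.2 are both named), STAR, Seurat and the mouse build mm10 are listed per the submitters' processing notes, with no role or order given for any of them. Whether the deposited matrices had been filtered for doublets, and which Cell Ranger version made which matrix, is not given in the sources used here. Version 7.1 counts intronic reads by default and 6.0.2 does not, so if each library was counted with a different version, the ratios would also carry that difference. After the results were seen, genes at 50 CPM or more in macrophage-like cells were split by span into 4 parts. The median log2 ratio was −0.01 in the shortest 25% and 0.10 in the longest 25%. Each matrix listed the same 31053 genes, of which 71 shared a symbol with another gene and were told apart by their Ensembl identifier. No column of per-sample values was left unmapped.

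Barcodes were kept with at least 200 genes detected and at most 20% mitochondrial UMIs. This left 4827 of 5252 barcodes in the knockout-labelled library and 4516 of 5081 in the wild-type-labelled library. Doublets were scored with Scrublet (scanpy 1.11.5) in each library. Its automatic threshold marked 0.124% and 0.0221% of cells, below the 0.5% set as the least that counts as working. The planned fallback therefore applied, and the cells with the highest 4% of scores were to be removed. This took out 181 cells (3.75%) and 168 cells (3.72%), and 4646 and 4348 cells were kept.

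Both libraries were clustered together without batch integration, on genes with a UMI in at least 3 cells. UMIs were scaled to 10000 per cell and log-transformed as log(1 + x). The 2000 most variable genes within each library were merged to 2989 genes, from which 30 principal components and a graph of 15 nearest neighbours were computed (scikit-learn 1.9.0, igraph 0.11.9). Leiden clustering (leidenalg 0.10.2) at resolution 0.8 gave 22 clusters. Markers of 30 cell classes (251 entries, 249 of them in the files) and 27 gene lists (348 entries, 345 in the files) were fixed before the data were examined. So were the main comparisons, the size rules and most of the other settings tried. Most tests of explanations and some checks were set later, as stated where they are given.

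The rule that turned markers into names was set after the data were examined, once 4 ways of computing the fold had been looked at (against all other cells or against cells outside the candidate class, with a pseudocount of 1 or 20 CPM). A cluster's candidate class was the one with the largest share of its markers detected in at least 25% of the cluster's cells, and at least 3 of them. It became the name where more markers of that class than of any other stood among the cluster's 10 leading genes. Folds used a pseudocount of 20 CPM against cells outside the candidate class. The rule named 16 clusters, 10 of them macrophage-like, and left 6 unnamed. All 6 unnamed clusters (3, 5, 6, 7, 12 and 20) had macrophage as their candidate class but as many or more monocyte or alveolar macrophage markers in the lead. Cluster 12 was also shallow, with a median of 1051.5 UMIs per cell. The unnamed clusters held 36.4% of kept cells in the knockout-labelled library and 18.0% in the wild-type-labelled library. Because a cluster's leading genes can also differ between libraries, each cluster was sought again after its own 100 leading genes had been taken out of the variable genes. It counted as found again where the overlap of cells (Jaccard index) reached 0.5. This step was added after seeing the data. Other genes that differ between libraries stayed in, so it cannot exclude clusters set by the library.

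Each genotype had 1 library, and cells of the same animal or suspension are not replicates. No test, p-value or standard error was therefore computed, and no difference has a replicate check. UMIs were summed over the cells of a class in each library, and expressed as CPM, the usual scaling of counts to a common total. The log2 ratio of the knockout-labelled over the wild-type-labelled library used a pseudocount of 1 CPM. Exact Poisson intervals of levels and exact conditional intervals of ratios (without pseudocount), and Clopper-Pearson intervals of shares, all at 95%, cover counting error only (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19). Genes were counted as higher or lower where the libraries lay at least 2-fold apart at a mean of at least 50 CPM, with mitochondrial, ribosomal protein, Gm- and Rik-named genes left out.

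The genes named were the 10 with the highest and the 10 with the lowest ratio in macrophage-like cells at that level, and the 5 and 5 over whole libraries. The same gene classes were left out. The rule added Msr1 and the other class A scavenger receptors, and the 2 highest and 2 lowest measured members of each list. Genes named outside this rule are marked as such. Not every gene that the rule picks is reported here. A list's median was taken over members with at least 10 CPM on average, and set against 10000 random lists of the same size drawn from 20 bins of mean expression. Its counting interval came from 1000 Poisson draws. A list was described as standing apart where its median lay outside the middle 95% of the random lists. Its place under each other setting, among random lists drawn anew, was added after the results were seen. Named classes other than macrophage-like cells had under 100 cells in at least 1 library. Genes and lists were therefore not compared within them, including T cell genes in T cells and milk protein genes in epithelial cells. Of the unnamed clusters, only cluster 3 had at least 100 cells in both libraries, and it was compared. Levels of a few genes, and ratios of Mtus1, heat shock and immediate early genes, were computed in epithelial-like cells as checks.

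Shares of cells with UMIs were compared after thinning each cell to 2000 UMIs. Thinning left out 471 cells (10.1%) of the knockout-labelled library and 236 (5.43%) of the wild-type-labelled library. Gene positions came from the GRCm38 annotation (GENCODE vM21), the same build as mm10, in which 30934 of the 31053 identifiers (99.6%) had a position.

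The steps were tested on simulated data, with gene means and depths set from the real counts of both libraries. Of 3143 genes in that test, all 133 changed 2.5-fold or more passed the 2-fold rule. None of 67 genes changed 1.5-fold passed it, nor did any of 2943 unchanged genes, and 95.2% of intervals held the simulated ratio. In the list step, 8 of 200 unchanged lists lay outside the middle 95%. Those lists were random genes with independent simulated counts, so this checks the computation only. It does not show how often lists of genes that vary together fall outside.

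Other settings chosen in advance were no cell filter, a stricter filter (500 genes, 10% mitochondrial UMIs), doublets kept, resolutions 0.4 and 1.5, each library clustered on its own, a macrophage class set per cell (UMIs of at least 3 macrophage markers), TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0; R 4.3.3), a gene floor of 50 CPM, thinned cells and the mean over cells. A class of all clusters with macrophage as candidate, and both libraries weighted to the same mix of clusters, were added after seeing the data. The weighted setting used the macrophage-like clusters with at least 100 cells in both libraries. Scripts ran under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.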

Results

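Single cells were profiled from female mice carrying the MMTV-PyMT transgene, which expresses the polyoma middle T oncogene in the mammary epithelium and gives rise to mammary tumours. They were labelled as lacking or keeping Msr1, which encodes the class A scavenger receptor SR-A, a macrophage surface receptor that binds modified lipoproteins and microbial ligands. The comparison bears on how SR-A shapes breast tumour progression and the macrophages of tumour-bearing mice. There was 1 library per genotype. The library labelled SR-A knockout held 5252 barcodes and 40099914 UMIs, and the library labelled SR-A wild type held 5081 barcodes and 44071314 UMIs. After filtering, 4646 and 4348 cells were kept, with a median of 7460 and 8745 UMIs per cell and a median mitochondrial share of 3.06% and 3.04%.

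The labels gave conflicting accounts of the population of the libraries. Both titles name macrophages and both give lung as the source, while the cell type tag reads EpCAM-positive tumour cells for the knockout and lung cells for the wild type. Genotype, population, gate and library therefore coincide, and every difference given here is between 2 libraries. With 1 library per genotype there is no replicate check and no test, and all intervals are 95% and cover counting error only. Of the 2 Cell Ranger versions named, only the later counts intronic reads by default, and which version counted which library is not given. Of 34 fixed markers of alveolar epithelial, club and ciliated cells, 22 stood under 1 CPM (UMI counts scaled to a common total) in both libraries and 9 at 10 CPM or more in at least 1, among them Napsa at 83.6 and 63.2 CPM. Sftpc, the surfactant protein of alveolar type 2 cells, had 0 and 1 UMIs in the knockout-labelled and wild-type-labelled library, with upper bounds of 0.0984 and 0.137 CPM. Scgb1a1 of club cells had 1 UMI in each. These 3 genes were singled out from the fixed markers, and the count was made, after their values were seen.

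Msr1 tags were present at similar levels in the macrophage-like cells of both libraries. Msr1 (ENSMUSG00000025044) lies on the minus strand of chromosome 8 at 39581685 to 39642673 (GRCm38), and its longest annotated transcript has 10 exons. Macrophage-like cells of the knockout-labelled library held 1596 Msr1 UMIs, 63.0 CPM (60.0 to 66.2). Those of the wild-type-labelled library held 1733 UMIs, 57.2 CPM (54.5 to 59.9), a log2 ratio of 0.14 (0.04 to 0.24). Over whole libraries the levels were 71.2 and 81.7 CPM, a log2 ratio of −0.20 (−0.27 to −0.12). In the unnamed clusters Msr1 stood at 98.9 CPM in the knockout-labelled library and 245.0 CPM in the wild-type-labelled library. Epithelial-like cells, which should lack the gene, held 7 and 3 UMIs, 6.84 and 0.950 CPM.

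After thinning to 2000 UMIs per cell, 12% (10.8 to 13.3) of macrophage-like cells had an Msr1 UMI in the knockout-labelled library and 9.55% (8.53 to 10.6) in the wild-type-labelled library. Unthinned, the shares were 33.8% and 30.2% at median depths of 8628 and 8975 UMIs. Among thinned epithelial-like cells the shares were 2.67% and 0.465%, and unthinned 9.33% and 1.40% at median depths of 12237 and 11781 UMIs. The labels name the knockout allele but not the exons it disrupts, and a 3' tag outside the disrupted part checks nothing. Msr1 therefore did not check the genotype labels, and "labelled" is kept throughout. The direction of the Msr1 ratio in macrophage-like cells depended on the setting, from −0.29 with all clusters that had macrophage as candidate class to 0.34 in thinned cells.

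Among the other class A scavenger receptors, Colec12 had 112 and 246 UMIs in macrophage-like cells, 4.42 and 8.11 CPM, below the floor for a measured gene. Marco had 1 UMI in each library, Scara3 had 0 and 1, and Scara5 had none in either.

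**Figure D1:**
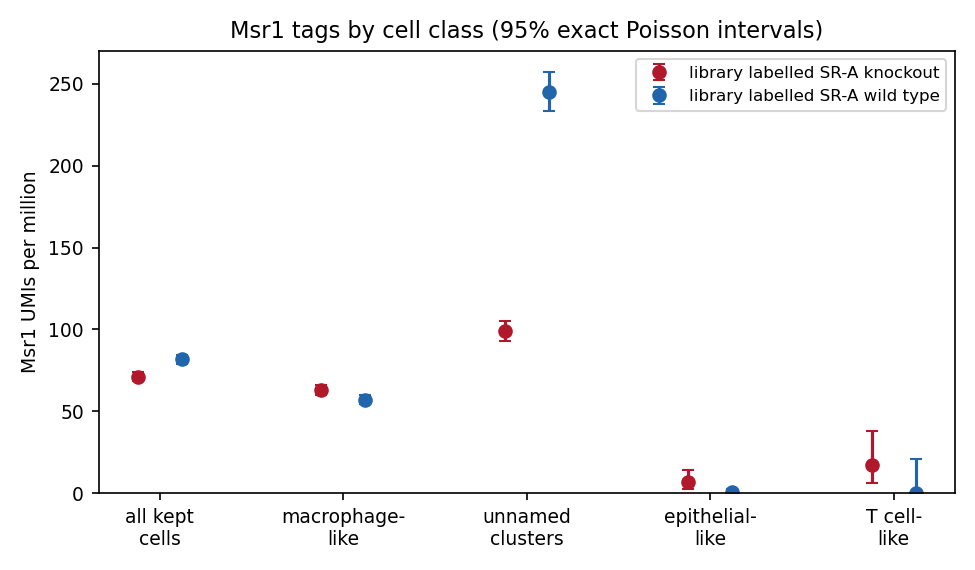
Msr1 CPM in all kept cells and in 4 classes of each library, with exact Poisson intervals (counting error only). Macrophage-like cells stood at 63.0 and 57.2 CPM, the unnamed clusters at 98.9 and 245.0, and epithelial-like cells at 6.84 and 0.950.

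Macrophages dominated both libraries. Macrophage-like clusters, led against other cells by complement C1q genes, Apoe and MHC class II genes, held 59.3% (57.8 to 60.7) of kept cells in the knockout-labelled library and 72.8% (71.5 to 74.2) in the wild-type-labelled library. Unnamed clusters with macrophage as their candidate class held a further 36.4% (35.0 to 37.8) and 18.0% (16.9 to 19.2). Taken with these, the shares were 95.6% (95 to 96.2) and 90.8% (89.9 to 91.7), so the order of the libraries depended on the rule that named clusters. Epithelial-like cells, with Epcam, Krt8 and the milk protein gene Csn3, made up 1.61% (1.27 to 2.02) and 4.95% (4.32 to 5.63). Neutrophil-like cells made up 0.0861% (0.0235 to 0.220) and 2.16% (1.75 to 2.64), as 4 and 94 cells. T cell-like cells were at 1.44% and 0.943%, B cell-like cells at 0.818% and 0.230%, and fibroblast-like cells at 0.409% and 0.897%. No cluster was named as lung epithelium or endothelium. A gate or dissociation that differed between the suspensions can set such shares, and the labels' differing tags leave that open. The knockout-labelled library, tagged EpCAM-positive tumour cells, held 1.61% epithelial-like cells, the lower share of the 2 libraries. Its cells therefore do not bear out that tag. Most cells of both libraries carried macrophage markers, and both titles name macrophages.

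Several kinds of macrophage-candidate cluster differed in share between the libraries. To see whether they rested on their leading genes, clusters were sought again without their own 100 leading genes, and 15 of 22 were found again. Other genes that differ between libraries stayed in, so a cluster set by the library can still be found again. Cluster 3, led by Ccl8, Folr2, Cbr2 and Lyve1, genes of tissue-resident macrophages, held 11.99% (11.1 to 12.96) of the knockout-labelled library and 1.22% (0.914 to 1.59) of the wild-type-labelled library, against 15.9% and 3.34% before its leading genes were taken out. Cluster 5, led by the monocyte genes Plac8, Ly6c2 and Chil3, held 6.59% (5.89 to 7.34) and 1.40% (1.08 to 1.80), against 10.01% and 1.79% before. Cluster 7, led by Lyz1, Retnla and Ear2, held 5.66% (5.01 to 6.36) and 1.63% (1.28 to 2.06). Cluster 6, led by Arg1, which degrades arginine, and the chemokine genes Pf4 and Cxcl3, held 0.387% (0.230 to 0.612) and 8.07% (7.28 to 8.92). Of the macrophage-like clusters, cluster 0 (Gpr137b, Apbb2) held 9.54% and 28.5%, cluster 1 (Hsph1, Hspa1b) 9.60% and 16.2%, and cluster 2 (Gdf15, Clec12a) 13.5% and 5.98%. Clusters 4, 9, 11, 13, 16, 20 and 21 were not found again, and their shares of the libraries are not given. For clusters 0, 1, 2, 6 and 7 the order of the libraries was the same before. A cluster held mostly by 1 library, such as cluster 6, can reflect that library and not a cell type.

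**Figure D2:**
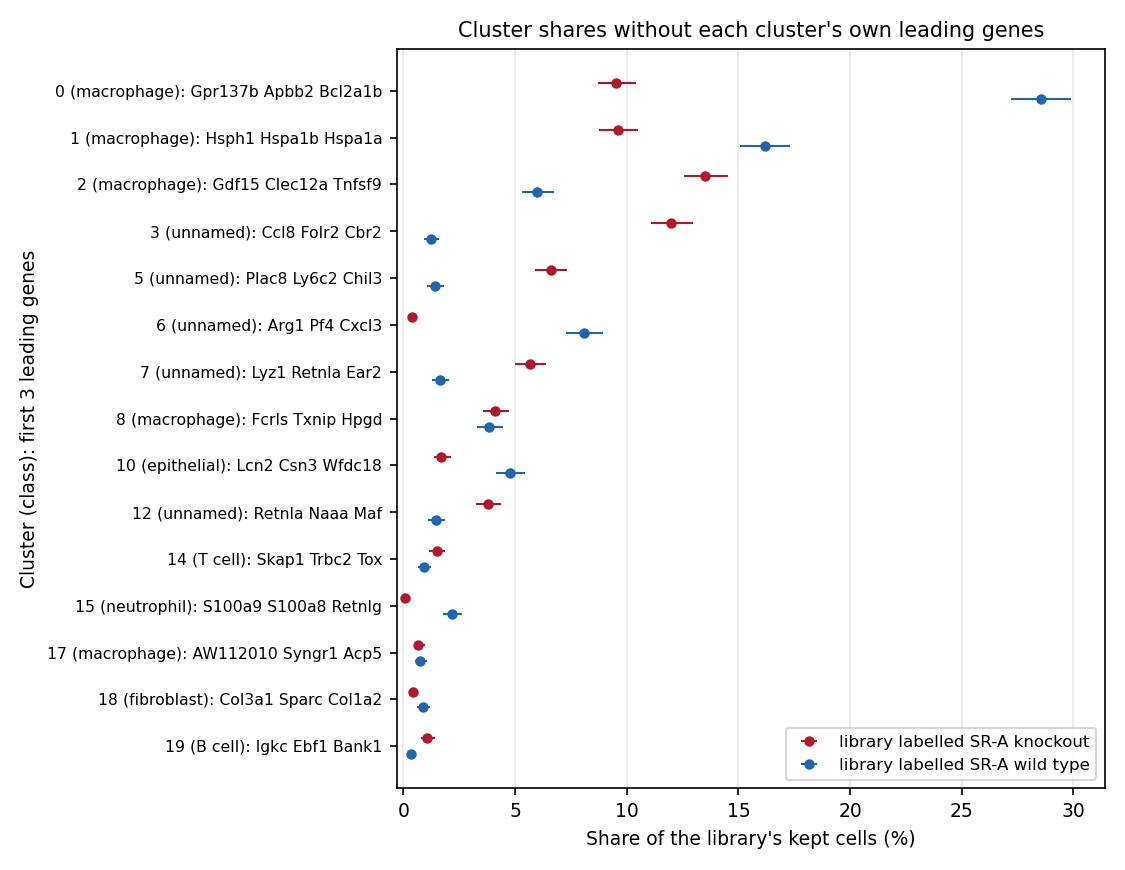
Share of each library's kept cells (%) in the 15 clusters found again without their own leading genes, with Clopper-Pearson intervals (counting error only). Cluster 3 held 11.99% of the knockout-labelled and 1.22% of the wild-type-labelled library, against 15.9% and 3.34% with those genes, and cluster 6 held 0.387% and 8.07%.

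Within macrophage-like cells, Gpnmb, Ly6a and Dnase1l3 had the highest ratios of the knockout-labelled over the wild-type-labelled library, and Mtus1 and heat shock genes the lowest. Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, stood at 97.1 CPM in the knockout-labelled and 2.94 in the wild-type-labelled library, a log2 ratio of 4.64. Ly6a, the interferon-inducible surface antigen Sca-1, had a log2 ratio of 2.39 (2.32 to 2.55), and Dnase1l3, a secreted DNase, of 2.14 (2.07 to 2.30). Hspa1a, an inducible HSP70 chaperone, stood at 219 and 705 CPM, a log2 ratio of −1.68 (−1.73 to −1.64). Mtus1, a microtubule-associated protein gene, had a log2 ratio of −1.53 (−1.69 to −1.44).

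Of 3008 genes at 50 CPM or more (mitochondrial, ribosomal protein, Gm- and Rik-named genes left out), 31 were at least 2-fold higher and 8 at least 2-fold lower in the knockout-labelled library. The other genes with the highest ratios were S100a6 (1.66), the matricellular gene Spp1 (1.65), the interferon-inducible genes Ifi27l2a (1.45) and Slfn5 (1.36), the inhibitory lectin receptor gene Clec12a (1.38), the T cell chemoattractant Cxcl9 (1.32) and Mthfsl (1.295). Those with the lowest included the chaperone genes Hspa1b (−1.49), Bag3 (−1.45), Hsph1 (−1.21) and Dnajb1 (−1.16). Gadd45g (−1.23), Tmx4 (−1.08), Pla2g7 (−0.99), encoding a lipoprotein-associated phospholipase, and Dmxl2 (−0.97) completed them. Hspa1a and Hspa1b are near-identical copies, so the split of tags between them is uncertain. Mtus1 (ENSMUSG00000045636) lies on chromosome 8 at 40990914 to 41133726, 1.45 Mb from Msr1. The 5 heat shock genes also had a median log2 ratio of −0.64 in cells outside the clusters with macrophage markers, with Hsph1 at 0.09 (−0.23 to 0.41). Of these 203 and 399 cells, 4 and 94 were neutrophil-like. With both libraries weighted to the same mix of the other classes the median was −0.69. In thinned cells of the unnamed clusters, which are not among these, Hspa1a stood at 224.7 and 213.2 CPM.

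The class was spread over its clusters differently in the 2 libraries. Cluster 2 made up 22.6% of macrophage-like cells in the knockout-labelled library and 9.38% in the wild-type-labelled library. Clusters 0 and 1 made up 14.5% and 16.4% against 43.3% and 24.2%. Gpnmb and Spp1 led cluster 13, not found again, whose 103 and 11 cells held 2187 of 2459 and 25 of 89 Gpnmb UMIs, and 12970 of 15609 and 1491 of 5952 Spp1 UMIs. These cluster values were looked up after the ratios were seen. Over whole libraries Spp1 stood at 471.8 and 584.0 CPM. Dnase1l3 led cluster 4, Clec12a led cluster 2, and Hsph1, Hspa1b, Hspa1a, Bag3 and Dnajb1 led cluster 1. When both libraries were weighted to the same mix of clusters, without clusters 13, 16 and 17, 4 of the 31 higher genes were still at least 2-fold higher and 30 were above 0, while all 8 lower genes were still at least 2-fold lower. Counted anew at 50 CPM or more, which 2 of those 4 no longer reached, 2 genes were at least 2-fold higher and 10 at least 2-fold lower. Of the 7 clusters weighted, 4, 9 and 11 had not been found again. Under that weighting the log2 ratio of Gpnmb was 1.73 and that of Spp1 was −0.63, while Ly6a was at 1.51, Dnase1l3 at 1.71, Hspa1a at −1.60 and Mtus1 at −1.56. Spp1 was also at −0.47 with doublets kept, −0.05 with the class set per cell and 0.11 with all candidate clusters, so its direction depended on the setting. Gpnmb was at 1.85 with doublets kept, Ly6a at 1.43 per cell, and S100a6 at 0.29 per cell, 0.55 with all candidate clusters and 0.90 at the same mix.

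**Figure D3:**
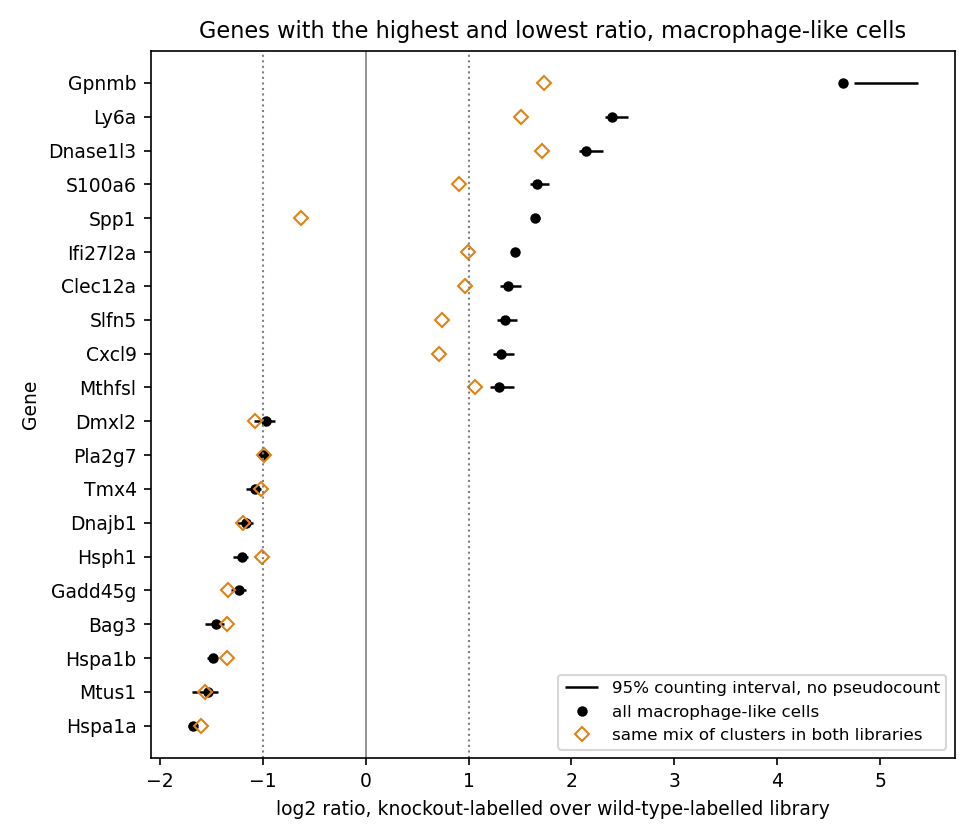
Log2 ratio (knockout-labelled over wild-type-labelled) of the 10 highest and 10 lowest genes in macrophage-like cells, with counting intervals as lines and the value at the same mix of clusters as diamonds. Points use a pseudocount and the lines do not, so the point of Gpnmb (4.64) lies left of its line (4.74 to 5.37), and Spp1 is at 1.65 and, at the same mix, −0.63.

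Summed over macrophage-like cells, monocyte-derived, interferon-stimulated and alternative activation genes were higher in the knockout-labelled library, and glycolysis genes were lower. All 5 measured monocyte-derived genes were above 0, 3 of them at least 2-fold, with a median log2 ratio of 1.23 (1.15 to 1.31). They included Ly6c2 (2.68) and Plac8 (1.94). Ly6c2 had a UMI in 3.09% of thinned macrophage-like cells in the knockout-labelled and 0.39% in the wild-type-labelled library. Of 18 interferon-stimulated genes 17 were above 0 and 4 at least 2-fold higher, with a median of 0.64 (0.57 to 0.71). Zbp1, a nucleic acid sensor, was at 1.16 and Ifi44 at 1.15, whereas Oasl1 was at −0.21. Of 10 alternative activation genes 8 were above 0 and 3 at least 2-fold higher, with a median of 0.73 (0.60 to 0.85), led by the lectin gene Mgl2 (1.64) and the transcription factor gene Egr2 (1.38). Within the 8 clusters with at least 100 cells in both libraries, the median of this list was above 0 in 5 and below 0 in 3. It was −0.21 in cluster 0 and −0.26 in cluster 1.

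Glycolysis and hypoxia genes had a median of −0.45 (−0.52 to −0.42), with 11 of 13 below 0, including the mitophagy receptor gene Bnip3 (−0.88) and Tpi1 (−0.71) of glycolysis. Ndrg1 of the same list was at least 2-fold higher (1.03). All 8 measured cholesterol synthesis genes were above 0, with a median of 0.43 (0.37 to 0.50), including Fdps at 0.91 and Cyp51 at 0.58. Of 12 MHC class I presentation genes 11 were above 0, with a median of 0.34 (0.31 to 0.36), led by H2-Q7 (1.03), a member of a multigene family whose tags can be split, and the transactivator Nlrc5 (0.95). The 9 MHC class II genes had a median of 0.12 (0.11 to 0.16), with the transactivator Ciita at 0.89 and H2-Ab1 at 0.28. As reported, this list stayed within the middle 95% of random lists, at percentile 96.6. It lay above it with doublets kept (98.5), the class set per cell (99.8) and a floor of 50 CPM (99.7). The same held with all candidate clusters (99.35) and at the same mix of clusters (99.45). Under the remaining settings it stayed inside, down to 78.1 with each library clustered on its own.

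Lysosomal genes and genes of lipid-associated macrophages were slightly lower as lists. Of 16 lysosome and cathepsin genes 13 were below 0, with a median of −0.16 (−0.18 to −0.15), but −0.07 at the same mix of clusters, including the protease gene Lgmn (−0.47) and Ctsa (−0.34). The list of lipid-associated tumour macrophage genes had a median of −0.23 (−0.25 to −0.20), with 10 of 15 below 0, and ranged from −0.54 with doublets kept to −0.11 with each library clustered on its own. Mmp12, macrophage elastase, was at −0.91 and Cd63 at −0.58, although Gpnmb and Spp1 of this list were 2 of the genes with the highest ratios. Lipid efflux and storage genes had a median of −0.19 (−0.22 to −0.12), but −0.07 with the class set per cell and 0.02 with each library clustered on its own, with the apolipoprotein gene Apoe at −0.53 and Fabp5, a fatty acid carrier, at 0.98. The 8 measured scavenger receptors outside class A had a median of −0.16 (−0.19 to −0.08), with Scarb2 at −0.24 and Cxcl16 at −0.24, while the oxidized lipoprotein receptor gene Olr1 was at 0.84 and Mrc1 at 0.39. Immediate early and heat shock genes had a median of −0.21 (−0.23 to −0.20), with Hspb1 at −2.01 and the immediate early gene Egr1 at 1.00. It was −0.01 at a floor of 50 CPM and −0.09 with each library clustered on its own. Within the 8 clusters with at least 100 cells in both libraries it ran from −1.07 to 0.08, below 0 in 6.

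Proliferation lists lay above 0, with a median of 0.59 (0.49 to 0.67) over 13 S phase genes, among them Mcm5 (0.87) and Uhrf1 (0.86), and of 0.45 (0.38 to 0.56) over 13 G2 and M phase genes, among them Mki67 (0.88) and Top2a (0.74). At the same mix of clusters the G2 and M median was 0.13. The share of thinned macrophage-like cells with at least 2 UMIs of the G2 and M list was 16.7% (15.3 to 18.1) in the knockout-labelled and 20.1% (18.7 to 21.5) in the wild-type-labelled library. Unthinned, it was 51.0% and 65.6%. These shares go against the summed levels. They also count cells outside cluster 9, whose leading genes include Top2a and Mki67. That cluster made up 6.6% and 4.7% of macrophage-like cells, in the order of the summed levels, but was not found again. No order in cycling was read. Chemokine genes had a median of 0.29 (0.26 to 0.31), with the monocyte chemoattractants Ccl8 at 1.28 and Ccl7 at 1.18. Classical inflammatory genes had a median of 0.22 (0.19 to 0.29), but 0.09 at the same mix of clusters, with the costimulatory gene Cd80 at 1.17, Il1a at −0.40 and Tnf at 0.03. Tissue-resident macrophage genes had a median of 0.36 (0.30 to 0.40), with F13a1 at 0.88, Folr2 at 0.60 and Selenop at −0.27. That median was 0.72 with all candidate clusters, while it turned below 0 at the same mix of clusters.

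Of the 25 lists with at least 3 measured genes, 16 lay outside the middle 95% of random lists of the same size and expression, all of them named above. Placed among random lists under each other setting, only 6 stayed outside wherever a value was given: interferon-stimulated, MHC class I, monocyte-derived, cholesterol synthesis, glycolysis and S phase genes. The other scavenger receptors did so in 5 of 14 settings, lipid efflux and the immediate early and heat shock list in 10, and classical inflammatory and lysosome genes in 12. Lipid-associated macrophage, alternative activation, chemokine, tissue-resident and G2 and M genes did so in 13. The remaining medians were 0.33 for 3 milk protein genes, 0.20 for 6 mesenchymal genes, led by S100a4 (1.68), 0.11 for 3 T cell exhaustion genes, 0.04 for efferocytosis, 0.03 for checkpoint ligands, 0.02 for matrix remodelling, −0.01 for the respiratory chain and −0.04 for complement. In the complement list C3 was at 1.54 and C1qc at −0.18. Class A scavenger receptors and cytotoxicity had 1 measured gene each, Msr1 (0.14) and Ccl5 (0.33). At the same mix of clusters the medians moved to 0.20 for interferon-stimulated, 0.68 for monocyte-derived and 0.36 for alternative activation genes. Monocyte-derived genes were at 0.39 with the class set per cell and 0.41 with all candidate clusters. Alternative activation genes ranged from 0.15 at a floor of 50 CPM to 1.42 with each library clustered on its own. Under that weighting chemokine genes were at −0.08 and tissue-resident genes at −0.17, on the other side of 0.

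**Figure D4:**
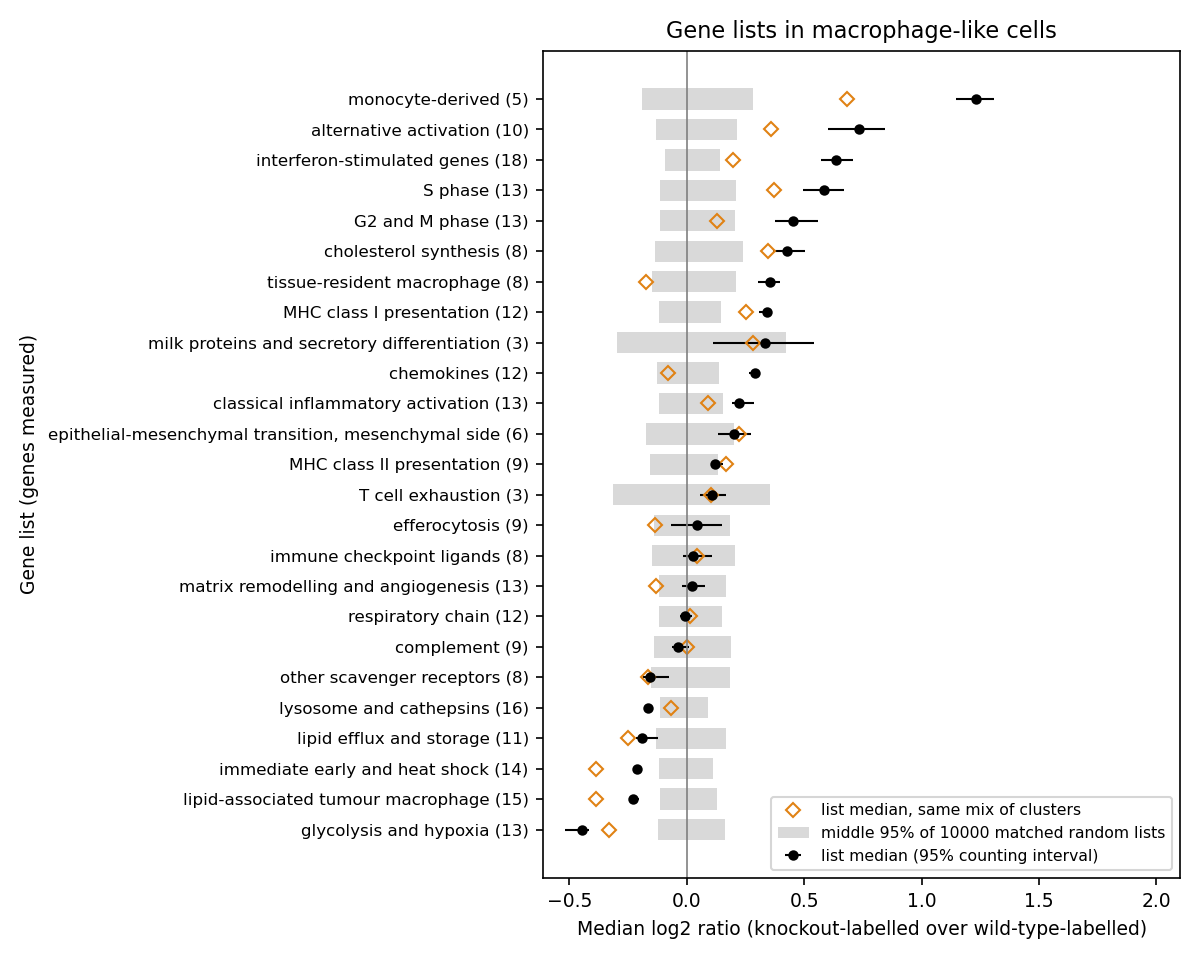
Median log2 ratio (knockout-labelled over wild-type-labelled) of each gene list in macrophage-like cells, with counting intervals, the middle 95% of matched random lists and the value at the same mix of clusters. Monocyte-derived genes had a median of 1.23 and glycolysis and hypoxia genes of −0.45.

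Compared cluster by cluster, some lists kept the same direction and others did not. In the 8 macrophage-candidate clusters with at least 100 cells in both libraries (0, 1, 2, 3, 4, 8, 9 and 11), glycolysis and hypoxia genes had a median below 0 in all 8, from −0.76 to −0.09. MHC class I genes were above 0 in all 8, from 0.10 to 0.37, as were MHC class II genes, from 0.08 to 0.46, and cholesterol synthesis genes, from 0.13 to 0.71. Scavenger receptors outside class A were below 0 in all 8, from −0.36 to −0.01, but outside the middle 95% of random lists only in clusters 0 and 3. MHC class I genes lay outside it in 7 of the 8, and glycolysis, MHC class II and cholesterol synthesis genes in 5 each. Interferon-stimulated genes were above 0 in 7, up to 0.91 in cluster 8 (Fcrls, Txnip), and at −0.67 in cluster 4 (Dcstamp, Dnase1l3). Monocyte-derived genes were above 0 in 6 of the 7 clusters with at least 3 measured genes, S phase genes in 7 of 8, alternative activation genes in 5, and tissue-resident and chemokine genes in 3 each. G2 and M phase genes were above 0 in 1 of the 4 clusters with at least 3 measured genes, and clusters 4 and 8 had only 3. Cluster 9 was itself led by G2 and M genes and cluster 11 by interferon-stimulated genes. Ratios of these lists within those clusters, or at the same mix, are therefore not independent of the clustering. Clusters 4, 9 and 11 had not been found again. Mtus1 was lower in all 8, with log2 ratios from −2.38 to −1.36. The Msr1 log2 ratio was 0.38 in cluster 0, 0.22 in cluster 1 and 0.99 in cluster 4, and below 0 in the other clusters, down to −0.85 in cluster 3.

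**Figure D5:**
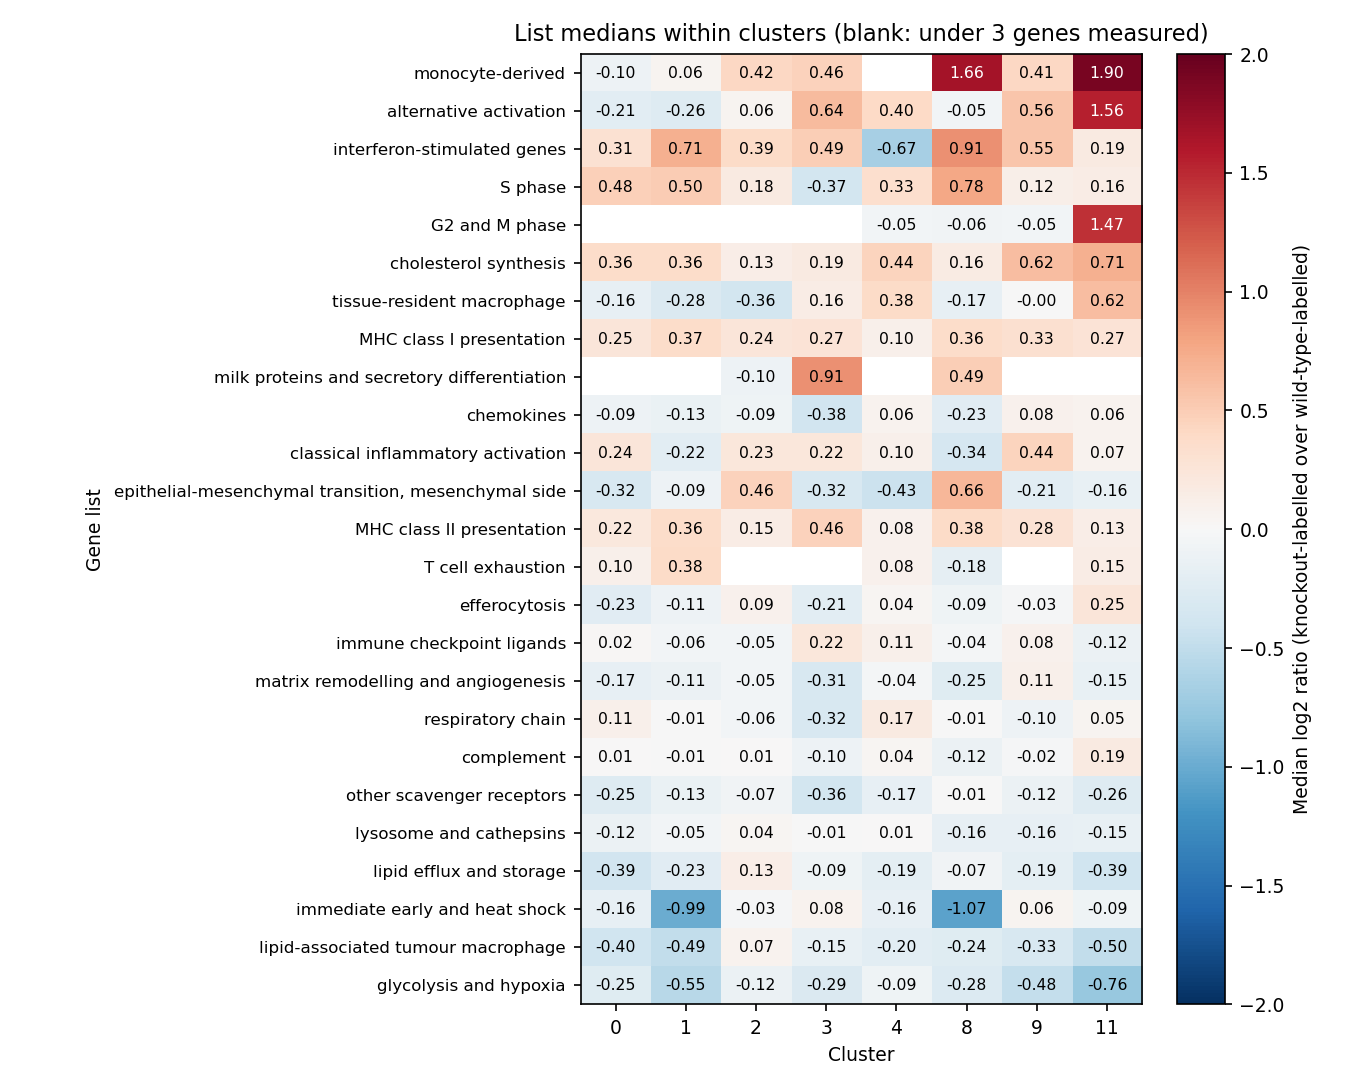
Median log2 ratio (colour, knockout-labelled over wild-type-labelled) of each gene list in the 8 clusters with at least 100 cells in both libraries, left blank where fewer than 3 genes were measured. Glycolysis and hypoxia genes were below 0 and MHC class I, MHC class II and cholesterol synthesis genes above 0 in all 8.

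Summed over all kept cells, which needs no clustering but moves with composition, 11 of 14 alternative activation and 9 of 10 tissue-resident macrophage genes were higher in the knockout-labelled library. Arg1, itself on the alternative activation list, S100a8, S100a9 and 6 of 7 milk protein genes were lower. The lectin gene Mgl2 stood at 110.9 and 20.4 CPM, a log2 ratio of 2.39 (2.34 to 2.56). Retnla stood at 1765 and 361 CPM (2.29), Ccl8 at 686 and 141 (2.28), with Clec10a at a log2 ratio of 2.19 and Ly6c2 at 2.11. The neutrophil calprotectin genes S100a9, at 1.55 and 284 CPM, and S100a8, at 1.04 and 159, had log2 ratios of −6.80 and −6.29. Arg1 stood at 19.3 and 324 CPM, a log2 ratio of −4.01 (−4.18 to −3.97), Hspb1 was at −1.78 and Lcn2, which led the epithelial-like cluster 10, at −1.70.

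Of 3157 genes at 50 CPM or more, 42 were at least 2-fold higher and 23 at least 2-fold lower. Neutrophil-like cells and cluster 6, with leading genes S100a9 and Arg1, held 4 and 15 cells of the knockout-labelled library and 94 and 405 of the wild-type-labelled library. In macrophage-like cells Arg1 stood at 20.9 and 7.95 CPM, with 439 of 529 and 56 of 241 UMIs in cluster 13. There it was lower in the knockout-labelled library (364 and 587 CPM), but from 103 and 11 cells of a cluster not found again. The unnamed clusters had 15.2 and 1968 CPM. These class and cluster values of Arg1 were looked up after its whole-library value was seen. Over whole libraries tissue-resident genes had a median log2 ratio of 0.72 (0.68 to 0.77), alternative activation genes of 0.75 (0.70 to 0.81), MHC class II genes of 0.31 (0.29 to 0.31) and glycolysis and hypoxia genes of −0.62 (−0.66 to −0.57). Milk protein genes had a median of −1.18 (−1.22 to −1.05), with 4 of 7 at least 2-fold lower, beside epithelial-like shares of 1.61% and 4.95%.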

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

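The setting with all macrophage-candidate clusters and the same mix of clusters were chosen after the results were seen, and the other 12 settings were planned. No paired analysis was possible because each genotype had 1 library and the results come from no test. The macrophage-like share of the knockout-labelled library was 53.1% with no cell filter, 62.1% with the stricter filter, 61.8% with doublets kept, 70.1% at resolution 0.4, 66.1% at 1.5, 76.6% with each library clustered on its own, 93.9% per cell, 62.9% in thinned cells and 95.6% with all candidate clusters. That of the wild-type-labelled library was 63.2% with no filter, 74.9% at resolution 0.4, 75.4% at 1.5, 78.8% clustered on its own, 92.2% per cell, 74.9% thinned and 90.8% with all candidate clusters. The knockout-labelled share was the higher of the pair in the per-cell class and with all candidate clusters. The Msr1 log2 ratio was 0.0195 with doublets kept, −0.26 per cell, 0.34 thinned, −0.29 with all candidate clusters and 0.0183 at the same mix. Genes at least 2-fold higher numbered 54 with each library clustered on its own and 2 at the same mix, and genes at least 2-fold lower numbered 15 per cell. TMM and median-of-ratios factors each gave 25 higher and 10 lower. The same mix leaves out clusters 13, 16 and 17, and with cluster 13 most Gpnmb (2187 of 2459) and Spp1 (12970 of 15609) UMIs of the knockout-labelled library. For the other shifts the cause was not tested. Chemokine and tissue-resident list medians reversed to −0.0792 and −0.173 at the same mix, and lipid efflux and storage to 0.0199 with each library clustered on its own, and the cause was not tested. Of 16 lists outside the middle 95%, 13 had the same sign in every setting that gave a value; S phase and cholesterol synthesis had no gene at the 50 CPM floor. Placed among random lists, a step added after the results were seen, 6 of the 16 lists stayed outside in every such setting and 10 lay inside or on the other side in at least 1. Over all lists, 167 of 376 values under other settings kept their sign within the counting interval, 169 kept it outside, and 40 in 12 lists had the other sign. At 1 library per genotype, depth narrows counting error only.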

Other observations

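The tests of free RNA, 3' ends, cluster mix, depth and handling were chosen only after the results were seen, while the bounds on the neighbours of Msr1 were set before the window value was computed, when Mtus1, Saraf and Nrg1 had already been seen to differ between the libraries.

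Over whole libraries, 8 of the 9 genes that led cluster 6 beside Arg1 were below 0, 2 of them at least 2-fold lower in the knockout-labelled library, and Ccl6 was above 0 (0.24). These genes were picked for standing high in a cluster of 15 and 405 cells. Lower values in the knockout-labelled library therefore largely follow from the choice. The neutrophil chemoattractant Cxcl3 stood at 2.67 and 46.9 CPM in the knockout-labelled and wild-type-labelled library, a log2 ratio of −3.71 (−4.44 to −3.85). Timp1, an inhibitor of matrix metalloproteinases, stood at 7.44 and 52.5 CPM (−2.67), and the platelet factor gene Pf4 at 351 and 692 CPM (−0.98). The resident macrophage gene Folr2 stood at 127 and 53.1 CPM, a log2 ratio of 1.245 (1.19 to 1.34). The monocyte chemokine receptor gene Ccr2 stood at 301 and 152 CPM (0.99), and Ciita, the MHC class II transactivator, at 116 and 56.4 CPM (1.03).

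In macrophage-like cells, genes near Msr1 on chromosome 8 differed in either direction. The growth factor gene Nrg1 stood at 21.7 and 4.62 CPM in the knockout-labelled and wild-type-labelled library, a log2 ratio of 2.02 (1.96 to 2.51), and it also stood among the leading genes of cluster 5. Saraf, a regulator of calcium entry, stood at 75.5 and 143.1 CPM (−0.91), and Asah1, the acid ceramidase of lysosomes, at 142.8 and 261.8 CPM (−0.87). These genes lie within 10 Mb of Msr1 and were picked after their values were seen.

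Msr1 tags were counted in both libraries, although 1 is labelled knockout. Free RNA from other cells, which would give like levels in all classes, is argued against by epithelial-like cells but not by every class. Msr1 was 9.21-fold (4.46 to 22.9) higher in macrophage-like than in epithelial-like cells of the knockout-labelled library. In the wild-type-labelled library it was 60.1-fold (20.5 to 291.8) higher. In the knockout-labelled library T cell-like cells stood at 17.5 CPM (6.42 to 38.1), but B cell-like cells at 127.1 (69.5 to 213.3), from 14 UMIs. Fibroblast-like cells there held 0 UMIs and neutrophil-like cells 2. C1qa, a macrophage marker, stood at 5287 CPM in thinned macrophage-like, 62.5 in B cell-like and 33.3 in epithelial-like cells of that library. Msr1 stood at 69.9, 62.5 and 13.3 CPM in these. The B cell-like Msr1 level is thus higher than macrophage RNA at the C1qa rate would give, though from 4 UMIs. It does not speak for free RNA from macrophages, which is not excluded for part of the Msr1 tags. Transcripts of the targeted allele that keep their 3' end may give these tags, as the locus spans 60.9 kb from first to last exon, but gene counts hold no position and the disrupted exons are not named in the labels. A wrong genotype label of 1 library stays open as well. The 33 measured genes within 10 Mb of Msr1 (Msr1 and Mtus1 left out) had a median absolute log2 ratio of 0.213. That lay at percentile 96.8 of 7470 windows, between the bounds set for either reading. The windows were centred on measured genes, overlap each other and hold differing numbers of genes (at least 10), so the percentile is coarse. Transcripts that keep their 3' end and a wrong label cannot be told apart without reads over the disrupted exons.

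Mtus1, 1.45 Mb from Msr1, was lower in macrophage-like cells of the knockout-labelled library. A different mix of clusters is argued against, because the log2 ratio was −1.36 or lower in each of the 8 clusters compared. Variants linked to the targeted allele are a candidate explanation, but the same neighbour test reached percentile 96.8 and missed its bound, and in epithelial-like cells Mtus1 was at 0.22 (−0.32 to 0.75). Linked variants and an effect of SR-A loss cannot be told apart with 1 library per genotype, and the biological explanation was not tested.

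Heat shock genes (Hspa1a, Hspa1b, Bag3, Hsph1 and Dnajb1) had a median log2 ratio of −1.45 in macrophage-like cells, with Dnajb1 below 0 in 6 of the 8 clusters and the others in all 8. The mix of clusters and the depth per cell are argued against for macrophage-like cells, since the median was −1.34 at the same mix and −1.43 in thinned cells. All these genes were among the leading genes of cluster 1, so the value at the same mix is not independent of the clustering. Handling before capture could contribute: in the 203 and 399 cells outside the clusters with macrophage markers the median was −0.64, past the bound of −0.5, although a requirement that epithelial-like cells also pass it, tried after the values were seen and then dropped, was not met (−0.47). Hsph1 was at 0.09 in these cells. Their differing classes did not account for the median, which was −0.69 at the same mix of classes without neutrophil-like cells. In thinned cells of the unnamed clusters, which are not among these cells, Hspa1a stood at 224.7 and 213.2 CPM. Summed there it was thus not lower, although it was below 0 in cluster 3, the only unnamed cluster compared. The test of handling covers the 203 and 399 cells only. Immediate early genes, which dissociation also induces, went both ways. Their medians were 0.06 in macrophage-like cells, −0.17 at the same mix of clusters and −0.21 in the other cells. At the same mix of classes of the other cells the median was 0.29, and −0.08 without neutrophil-like cells. Handling and genotype coincide in these 2 libraries, and the biological explanation was not tested.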
